A study of Homo sapiens with 6 samples.

How the data were processed

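RNA sequencing was carried out on 6 libraries of cultured primary human basal epithelial cells from lungs with idiopathic pulmonary fibrosis, 3 transfected with control siRNA and 3 with SOX9 siRNA, grouped by the labels. The labels name both as stealth siRNA. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat and DESeq and the genome build hg19, with no role or order. The quantification tool, the gene annotation and the strand setting are not given in the sources used here. Total RNA was extracted with a column kit, per the labels' protocols.

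The authors deposited 2 tables with 1762 genes each. The per-library values in them are not whole numbers and are rounded to 2 decimals, although the workbook is named for raw counts. They were taken as TPM made by the authors, an inference from the deposited values: for 391 genes with a single transcript in GENCODE release 29, the value times the transcript length in kb divided by the authors' CPM had a median of 2.53 (quartiles 2.38 and 2.85), where RPKM would give 1. TPM values keep no sequencing depth, so the depth of each library and the counting error are unknown. The deposited log2 fold change and log2 CPM, the likelihood-ratio score, the p-value and the FDR are the authors' own, per the file headers. Headers of a likelihood-ratio statistic and a log2 CPM do not say which tool made these columns, and whether it was the DESeq of the processing notes is not given in the sources used here. The ratio of FDR to p-value by rank gave 12256 genes as the number the authors adjusted over, so the table holds 14.38% of the genes tested, those with an FDR under 0.05. The second table gives a score, the Pearson correlation of each gene with SOX9 over the 6 libraries, per the file headers, and it was recomputed from the deposited TPM values to within 0.005. Gene symbols were used as the files give them, of which 1567 were found in the reference gene table. The files give no coordinates, and the reference used is of another build than hg19, so no positions are given.

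The design had assumed counts. As the tables hold TPM-type values of selected genes, the test named beforehand for normalized values was used: limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with the group as the only term, and Benjamini-Hochberg adjustment over the 1762 genes at a threshold of 0.05. A fold change on the log2(TPM + 1) scale understates the change of low genes, and ratios in the text are ratios of mean TPM. No filter on low values was applied. Because the genes had been selected by the authors on these libraries, adjusted p-values do not refer to the whole transcriptome. The method was tested on simulated data with the spread of the 1762 genes and 200 genes changed, over 20 runs: it recovered 45.1% of genes changed by 0.5, 84.4% of those changed by 1 and 96.6% of those changed by 2 on the log2 scale, and 4.93% of its calls were false. The simulated genes varied independently and most were unchanged, unlike the genes selected by the authors, so these shares need not hold for the real calls.

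The lists of genes were fixed before the data were examined, as were the groups, the rule for named genes and the first set of alternatives. There were 26 lists. For a list with at least 5 called members, the number of members called higher and lower was set against the other called genes by Fisher's exact test (two-sided), adjusted by Benjamini-Hochberg over the 11 lists tested. This test counts genes as independent, which list members that vary together are not, so its p-values can be too small. Tests that rank a list against all genes were not run, since the table holds selected genes. The named genes were SOX9, the 12 most positive and the 12 most negative log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 TPM and no overlap between the groups, and up to 4 called members with the smallest adjusted p of each list, leaving out sex-linked genes named in advance, clone names and symbols turned into dates. Not every gene the rule names is reported here. A further 5 lists were added after the data were examined.

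Alternatives were median-ratio scaling over the table's genes, equal column totals, a pseudocount of 0.1, a replicate block, each library left out in turn, thresholds of a log2 fold change of 1 or an adjusted p of 0.01, and list members with a log2 fold change of at least 0.58. Added after the data were examined were the scaling of the authors' fold changes, a mean of at least 1 TPM, a variance trend with robust estimation, adjustment over all 12256 genes, and the interferon list left out of the comparison genes. Bootstrap intervals used 10000 draws over genes at a level of 95%. Other tools were Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.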

Results

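RNA levels were measured by sequencing in primary basal epithelial cells, the progenitor cells that line the base of the airway epithelium, cultured from lungs with idiopathic pulmonary fibrosis (IPF), a progressive scarring disease of the lung. The cells had been transfected either with a control small interfering RNA (siRNA) or with an siRNA against SOX9, a transcription factor of lung development and cartilage formation, with 3 libraries in each of the 2 groups. The question was which transcripts differ when SOX9 is knocked down. The deposited tables hold 1762 genes that the authors kept from 12256 tested, with a TPM-type value, a length-scaled transcript abundance, per library. Over these genes the libraries summed to between 103132 and 108591 TPM, and the sequencing depth of the libraries is unknown, so no counting interval can be given. The labels do not say whether the libraries of a group came from separate donors or cultures, so limma p-values measure only the spread between these samples, which may be technical.

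SOX9 itself was lower in every SOX9 siRNA library. It was measured at 7.24, 8.27 and 6.41 TPM in the control libraries and at 1.97, 2.61 and 2.54 TPM in the SOX9 siRNA libraries. The mean fell from 7.31 ± 0.932 TPM to 2.37 ± 0.351 TPM (SD, n = 3 per group), a 3.08-fold lower level. The log2 fold change on the log2(TPM + 1) scale was -1.30 with a standard error of 0.14 (limma adjusted p = 0.00164). In the authors' deposited table the log2 fold change of SOX9 was -1.52 with a false discovery rate of 1.08e-13.

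In the SOX9 siRNA libraries interferon-stimulated antiviral genes were lower, cornified-envelope and other squamous differentiation genes were mostly higher, and called members of the unfolded protein and amino acid stress list were mostly lower. The direction of the last of these lists lost its call in 6 alternatives, for example without control replicate 2 (Fisher's exact test, adjusted p = 0.204). Of the 1762 genes, 1390 passed limma at an adjusted p under 0.05, of which 608 were higher and 782 lower in the SOX9 siRNA libraries, and 372 did not pass. The direction was that of the authors' deposited table for each of the 1762 genes. The authors' deposited table itself lists 939 genes as higher and 823 as lower, which is 53.3% higher, against 43.7% of the limma calls. Its log2 fold changes lie 0.10 above the log2 ratio of the TPM means in the median of 988 genes, and with the libraries put on that scaling limma called 858 genes higher and 721 lower. The 2 groups did not overlap for 1478 genes (83.9%), where chance alone gives 10% of genes, but the authors had selected these genes on the same 6 libraries, so neither this share nor the adjusted p-values are independent evidence of change. The number of calls was 896 without control replicate 2, 733 without control replicate 3 and 921 without SOX9 siRNA replicate 3, and it was 173 when the p-values were adjusted over all 12256 genes tested by the authors.

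Interferon-stimulated genes made up the group with the lowest values relative to control. Of the 41 genes of this list, 40 were in the table, and all 40 were lower and called, both over all genes tested and adjusted over the list alone, with a median log2 fold change of -2.63. With adjustment over all 12256 genes tested by the authors 16 of the 40 were called. Against the other called genes the 40 lower members were a shift to lower (Fisher's exact test, two-sided, adjusted p = 1.32e-09 over 11 lists). That p-value counts genes as independent, although these varied together across the libraries, so it does not measure the spread between libraries. IFIT2, an interferon-induced protein that restricts translation of viral RNA, fell from 76.5 ± 31.5 TPM to 3.53 ± 3.47 TPM (SD, n = 3 per group), which is 21.7-fold lower. IFIT1, which binds uncapped viral RNA, was 12.6-fold lower, and the dynamin-like antiviral GTPases MX1 and MX2 were 8.07-fold and 11.7-fold lower. RSAD2, which encodes viperin, fell 12.1-fold, the chemokine CXCL10 fell 14.4-fold, and OAS2, an enzyme that makes the activator of RNase L, fell 9.49-fold. USP18, which removes ISG15 from proteins and dampens interferon receptor signalling, fell from 13.2 ± 1.78 TPM to 2.01 ± 0.741 TPM (SD, n = 3 per group). IFI44L, IFIT3, IFI44, IFI6 and, outside the list, IFITM1 were also among the 12 lowest called genes, with log2 fold changes between -4.02 and -3.43. MX1, MX2, OAS2, IFI44, IFI6 and IFITM1 were not called with that wider adjustment (limma adjusted p between 0.0526 and 0.102). The level of this list also differed within the groups: as a median over the 40 genes, the SOX9 siRNA libraries held 5.1%, 33.0% and 9.6% of the control mean in replicates 1, 2 and 3, and the control libraries 66.8%, 112.9% and 120.7%. In 39 of the 40 genes SOX9 siRNA replicate 2 was above replicates 1 and 3, and in 39 control replicate 1 was below the other controls. Without SOX9 siRNA replicate 2 the median log2 fold change was -3.15, and all 40 genes remained called lower. The ratios of mean TPM then became 49.8 for IFIT2, 40.5 for IFIT1, 23.7 for MX1, 29.3 for MX2, 29.1 for RSAD2, 56.4 for CXCL10 and 24.4 for OAS2, as control over SOX9 siRNA.

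**Figure D1:**
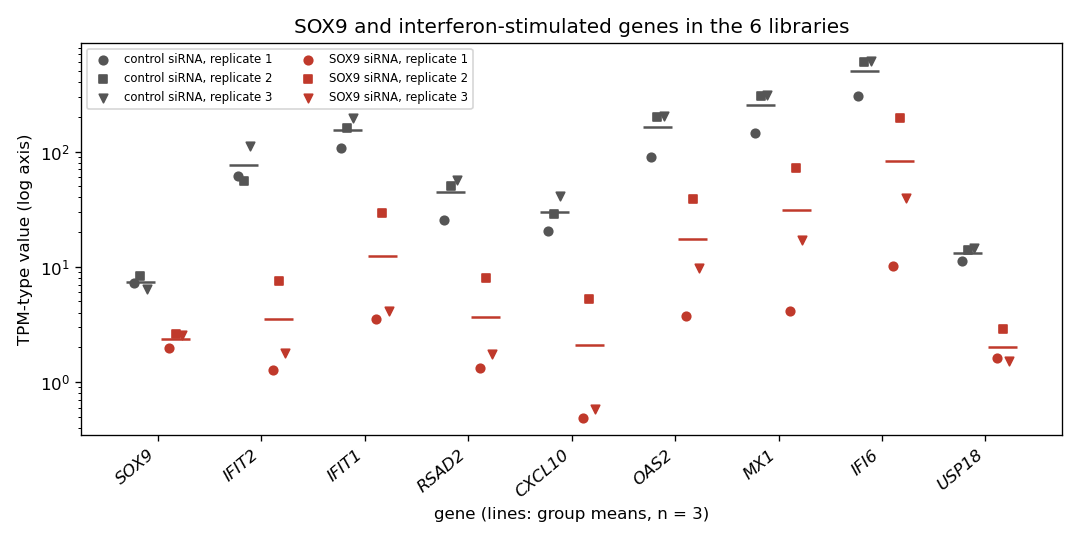
TPM-type values (log axis) of SOX9 and 8 interferon-stimulated genes in the 3 control siRNA libraries (grey) and the 3 SOX9 siRNA libraries (red), with marker shapes for replicates and lines for group means. The groups do not overlap for any gene shown, and SOX9 siRNA replicate 2 (red squares) lies above the other SOX9 siRNA libraries, for example IFIT2 at 7.52 TPM against 1.27 and 1.8 TPM.

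Squamous differentiation genes moved the other way. Of the 47 genes of this list 16 were in the table, of which 13 were called higher, 2 lower and 1 did not pass, and 15 were called adjusted over the list alone. With adjustment over all 12256 genes tested by the authors 8 were called higher and 0 lower. The median log2 fold change was 0.90, and the direction differed from that of the other called genes (Fisher's exact test, adjusted p = 0.00507). CRCT1, a gene of the epidermal differentiation complex, rose from 37.1 ± 8.04 TPM to 150.2 ± 6.54 TPM (SD, n = 3 per group). CNFN, which encodes the cornified envelope protein cornifelin, rose 4.30-fold, the kallikrein protease KLK6 rose 4.87-fold, and CDSN, which encodes the adhesion protein corneodesmosin, rose 4.60-fold. The 2 called members that fell, neither of them called with that wider adjustment, were S100A7, which encodes psoriasin, and CSTA, which encodes the protease inhibitor cystatin A. They lie outside the rule for named genes and were chosen after their values were seen, and their log2 fold changes were -1.13 and -0.81. Values of KRT6C, SPRR2A and SPRR2D are uncertain because each has close paralogs among which reads can be divided. Among the 12 highest called genes outside the list were LCE3D, a late cornified envelope gene, at 8.70-fold, the hair-follicle keratin gene KRT75 at 3.85-fold, MAL, which encodes a protein of apical membrane sorting, at 5.02-fold, KRTAP2-3 at 5.51-fold, FAM25A at 5.19-fold and TCRVB at 4.64-fold, the last at 10.1-fold without control replicate 1 and not called with the wider adjustment (limma adjusted p = 0.0949). DEFB103A, which encodes the antimicrobial peptide beta-defensin 3, was listed at 0 in the 3 control libraries and at 15.6, 6.84 and 13.0 TPM in the SOX9 siRNA libraries. A near-identical copy of this gene exists, so its level is uncertain.

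**Figure D2:**
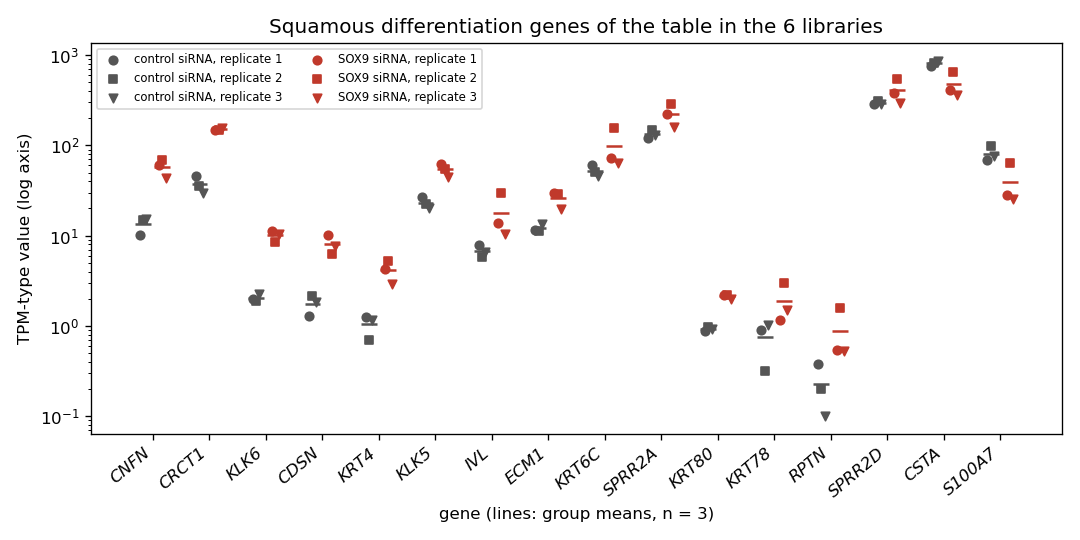
TPM-type values (log axis) of the 16 squamous differentiation genes of the table in the 3 control siRNA (grey) and 3 SOX9 siRNA (red) libraries, ordered by log2 fold change, with lines for group means. CRCT1 stands at 146.5, 146.4 and 157.8 TPM in the SOX9 siRNA libraries, above the highest control library at 45.7 TPM, while CSTA and S100A7 at the right lie lower in the SOX9 siRNA group.

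Genes of the unfolded protein and amino acid stress list were mostly lower. Of its 35 genes 17 were in the table, with 15 called lower, 1 higher and 1 not called, and 16 were called adjusted over the list alone. With adjustment over all 12256 genes 5 were called lower and 0 higher. The median log2 fold change was -0.80, and SOX9 siRNA replicate 2 was the highest of its group in 14 of the 15 lower genes. PSAT1, an enzyme of serine synthesis, fell from 25.97 ± 3.81 TPM to 8.51 ± 1.46 TPM (SD, n = 3 per group), and ALDH1L2, a mitochondrial enzyme of folate metabolism, fell 2.65-fold. SLC7A5, a transporter of large neutral amino acids, fell 2.13-fold, and STC2, a secreted glycoprotein gene, fell 2.02-fold. The 1 higher member, SDF2L1, which encodes a protein of the endoplasmic reticulum, was chosen after its value was seen (log2 fold change 0.61). The direction of the list passed the test (Fisher's exact test, adjusted p = 0.00608), but the call was not kept without control replicate 2 (Fisher's exact test, adjusted p = 0.204), control replicate 3 (0.114), SOX9 siRNA replicate 1 (0.0508) or SOX9 siRNA replicate 3 (0.0826), and the range over the alternatives was 0.00536 to 0.204.

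For the remaining 8 lists with at least 5 called members the direction did not pass the test. Of 59 extracellular matrix and fibrosis genes, 19 were in the table, with 11 lower, 3 higher and 5 not called (Fisher's exact test, adjusted p = 0.199), and 14 were called adjusted over the list alone. On the scaling of the authors' fold changes 8 were called higher and 11 lower. Its called members included THBS1, a matrix glycoprotein gene, which fell 1.91-fold, and LTBP1, which encodes a binding protein of latent TGF-beta and fell 1.71-fold. Among markers of the aberrant basaloid cells described in fibrotic lungs, 9 of 24 were in the table, with 5 higher, 1 lower and 3 not called (Fisher's exact test, adjusted p = 0.199), and 6 were called adjusted over the list alone. They included SLCO2A1, a prostaglandin transporter gene, at 2.69-fold and the tight junction gene CLDN4 at 2.03-fold. Without SOX9 siRNA replicate 3 the calls in this list were 3. Of 25 airway basal cell markers 6 were in the table, 2 higher and 4 lower (Fisher's exact test, adjusted p = 0.771), and all 6 were called adjusted over the list alone. DST, which encodes the hemidesmosome linker dystonin, fell from 655.0 ± 34.8 TPM to 241.6 ± 21.2 TPM (SD, n = 3 per group) and had a false discovery rate of 1.91e-46 in the authors' deposited table, and EGFR, the epidermal growth factor receptor gene, fell 1.47-fold. The calls among basal cell markers were 3 without control replicate 2 and 2 without control replicate 3. Of 25 MAPK/ERK feedback genes 6 were in the table, with 5 lower and 1 higher (Fisher's exact test, adjusted p = 0.33) and 6 called adjusted over the list alone. The transcription factor genes EGR1 and FOS fell 2.41-fold and 3.11-fold, and the EGFR ligand genes AREG and EREG fell 2.03-fold and 2.49-fold. Of 35 inflammatory cytokine and NF-kB target genes 12 were in the table, with 8 lower, 3 higher and 1 not called (Fisher's exact test, adjusted p = 0.447), and 12 were called adjusted over the list alone. The chemokine gene CCL20 fell 2.92-fold and CSF2, which encodes the growth factor GM-CSF, rose 3.27-fold. The YAP/TAZ targets gave 6 lower, 1 higher and 1 not called among 8 of 25 genes in the table, and the higher one was ANKRD1 at 4.43-fold (Fisher's exact test, adjusted p = 0.227). The 5 apoptosis regulators in the table, of 32, were all lower, BIRC3 among them at 2.74-fold (Fisher's exact test, adjusted p = 0.198). SOX9 siRNA replicate 2 was the highest of its group in all 5 of them and in 7 of the 8 lower inflammatory genes. Control replicate 1 was the lowest control in 4 and 7 of them, the order also seen in the interferon list. The order was not particular to these lists. Among the 15 lower stress genes control replicate 1 was the lowest control in 9, and among the 11 lower matrix genes in 3. SOX9 siRNA replicate 2 was the highest of its group in 14 and 7 of these. Some lists share genes, so their counts are not separate findings. CXCL10 stands in the inflammatory and interferon lists, BIRC3 in the inflammatory and apoptosis lists, and THBS1 and CTGF in the matrix and YAP/TAZ lists. The 5 Wnt pathway genes in the table, of 39, gave 2 higher and 3 lower (Fisher's exact test, adjusted p = 1). Adjusted over the list alone, 7 YAP/TAZ targets, 5 apoptosis regulators and 5 Wnt pathway genes were called. Without control replicate 3 the calls in these lists were 4, 3 and 2, without SOX9 siRNA replicate 1 or 3 there were 3 apoptosis and 3 Wnt calls, and the Wnt calls were 3 without control replicate 1 and 2 without control replicate 2. With adjustment over all 12256 genes the calls in these 8 lists were 3 matrix, 2 aberrant basaloid, 1 basal cell, 5 MAPK/ERK, 4 inflammatory, 2 YAP/TAZ, 1 apoptosis and 0 Wnt genes, and LTBP1 and EGFR were not called (limma adjusted p = 0.0543 and 0.0766).

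**Figure D3:**
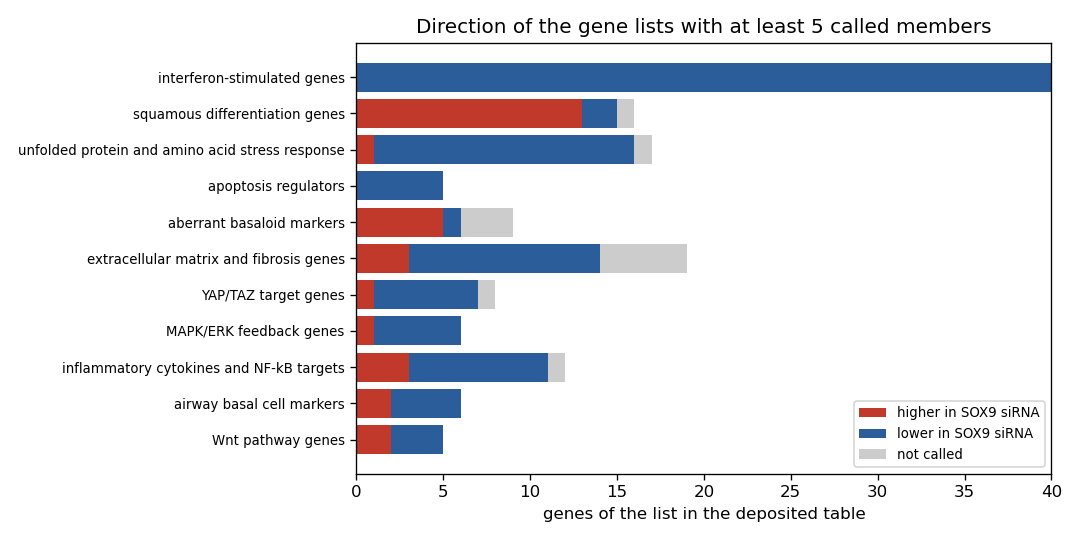
Number of genes of each list in the deposited table that were called higher (red) or lower (blue) in the SOX9 siRNA libraries by limma, or not called (grey), for the 11 lists with at least 5 called members. The interferon list has 40 lower and 0 higher genes and the squamous list 13 higher and 2 lower.

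Fewer than 5 members were called in the other lists, so their direction was not tested. The markers of other cell types in the table were 2 of 22 fibroblast and smooth muscle markers, TAGLN and LOX, both lower, 0 of 23 immune and endothelial markers, 1 of 23 ciliated cell markers and 4 of 26 secretory cell markers, of which 3 were called higher. Genes outside the table were not analysed here, so their levels are unknown. Of 18 alveolar epithelial markers 3 were in the table, with LAMP3, a lysosome-associated membrane protein gene, 6.19-fold lower and 2 others, HOPX and ETV5, higher, and none of the 3 was called with adjustment over all 12256 genes (limma adjusted p = 0.0538, 0.12 and 0.202). The 3 Notch pathway genes in the table, of 25, were all lower, with the ligand gene JAG1 falling 1.68-fold. Of 22 epithelial-mesenchymal transition genes 5 were in the table, 2 higher and 2 lower. The epithelial adhesion molecule gene EPCAM rose 1.89-fold and the mesenchymal marker gene VIM rose 1.32-fold. The epithelial regulator genes GRHL2 and ESRP1 fell 1.47-fold and 1.44-fold. VIM was not called without control replicate 2 or SOX9 siRNA replicate 3 (limma adjusted p = 0.0613 and 0.0581), nor ESRP1 without control replicate 3 (0.0544). Cell cycle genes were few, with 4 of 44 genes of G1/S and DNA replication (2 higher, 1 lower) and 2 of 49 genes of G2/M and mitosis (1 higher). Among 29 p53 targets 6 were in the table (2 higher, 1 lower), among 25 cholesterol synthesis genes 4 (1 higher, 1 lower), and among 31 hypoxia and glycolysis genes 5 (1 higher, 3 lower). Of 25 SOX factors and cartilage matrix targets of SOX9, SOX9 and SOX4 alone were in the table, the second of them 1.35-fold higher. SOX4 was not called without control replicate 3 or SOX9 siRNA replicate 3 (limma adjusted p = 0.0602 and 0.0545), and LOX was not called without control replicate 1, control replicate 2 or SOX9 siRNA replicate 1 (limma adjusted p = 0.0562, 0.052 and 0.0599). With adjustment over all 12256 genes neither was called (limma adjusted p = 0.116 and 0.148), nor was TAGLN (0.0702), and of the genes in these lists SOX9, JAG1 and EPCAM alone were called. None of 15 mitochondrially encoded transcripts and 2 of 11 genes of the siRNA machinery were in the table, the latter not called. Adjusted over the list alone, the counts of calls were 4 secretory, 1 ciliated, 3 alveolar, 2 fibroblast, 5 epithelial-mesenchymal, 4 G1/S, 1 G2/M, 3 p53, 2 cholesterol, 4 hypoxia, 3 Notch, 2 SOX and 2 siRNA machinery genes. These small counts rest on single libraries: without control replicate 3, for example, 0 ciliated, 1 alveolar, 1 Notch, 0 p53, 1 G1/S, 0 G2/M, 1 cholesterol and 2 hypoxia genes were called, and without control replicate 2 there were 1 secretory, 0 ciliated, 1 fibroblast, 1 G1/S, 0 G2/M and 2 hypoxia genes. Without SOX9 siRNA replicate 1 there were 1 fibroblast, 0 G2/M and 2 hypoxia genes, without SOX9 siRNA replicate 3 there were 1 G1/S and 0 G2/M genes, and 1 siRNA machinery gene was called higher without SOX9 siRNA replicate 2 or 3.

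The 6 libraries separated by siRNA. On the first principal component, which held 83.5% of the variance over the table's genes, the control libraries lay at -11.1, -18.3 and -19.7 and the SOX9 siRNA libraries at 23.3, 6.88 and 19 in replicates 1, 2 and 3, with SOX9 siRNA replicate 2 nearest to the controls. Pearson correlations across genes, which are not independent replicates, were 0.968 to 0.993 between libraries of a group and 0.872 to 0.962 between groups. These genes had been selected for a difference between the groups, which favours such a separation.

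The second deposited table gives the correlation of each gene with SOX9 over the 6 libraries and holds the same 1762 genes. A positive coefficient stands beside 825 genes and a negative one beside 937 in the authors' deposited table. Of the positive ones 823 were lower in the SOX9 siRNA libraries, and the 937 negative ones were higher, so the sign of the coefficient went with the group difference for all but 2 genes. The libraries fall into 2 separate clusters of 3 in their SOX9 level, so no pooled coefficient is given, and with 3 libraries in each cluster no coefficient within a cluster is given either.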

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

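Of the alternatives reported here, the scaling of the authors' fold changes, the mean of at least 1 TPM, the variance trend, the adjustment over all 12256 genes and the comparison without the interferon list were chosen after the data were examined. The fall of SOX9 kept its direction and stayed past the threshold in all 14 alternatives run for it, with log2 fold changes between -1.59 and -1.21. The count of 1390 called genes became 173 with adjustment over all 12256 genes (fewer pass because more tests are counted), 176 with a log2 fold change of at least 1, and 366 at an adjusted p under 0.01. With single libraries left out it ranged from 733 to 1281, with fewer samples in each fit. Of the 733 genes called without control replicate 3, 723 were also among the 1390. The number of lists past the threshold stayed at 2 or 3 of the fixed lists, and the interferon and squamous lists passed in every alternative run (Fisher's exact test, adjusted p at most 0.00307 and 0.044). The unfolded protein and amino acid stress list did not pass in 6 alternatives: the 4 left-out libraries given in the results, members with a log2 fold change of at least 0.58 (Fisher's exact test, adjusted p = 0.141) and adjustment over all 12256 genes (adjusted p = 0.173). Of 1244 values of the 89 other named genes under the alternatives 119 no longer passed, 50 of them with adjustment over all 12256 genes and 22 without control replicate 3, and 0 changed direction. With a replicate block limma called 1326 genes, the log2 fold change of SOX9 was -1.30 and 3 lists passed. Deviations from the group means of libraries with the same number correlated at 0.39, 0.32 and -0.22, so the numbers were not taken to pair the libraries, and 3 of the 6 libraries correlated best with their own number. Alternatives that need counts (another size factor method or count test, and a filter of 100 counts) were not run because the tables hold no counts, leaving out the filter equals the fit reported, and matching by identifier was not run because the tables give symbols alone. As the depth is unknown, its limit on low genes cannot be given.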

Other observations

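Of the tests in this part, the one of gene length and expression level was set before its result was seen, and the other tests, the 5 added gene lists and the upper limits of enrichment were chosen after the data were examined. The added lists were tested on libraries already seen, so none of their p-values is independent evidence of a change. Of 75 genes for lysosomal enzymes, membrane proteins and the proton pump, 23 were in the table, with 16 called higher, 0 lower and 7 not called by limma (Fisher's exact test, adjusted p = 6.42e-06 over 4 lists), and each of the 23 is higher in the authors' deposited table. The calls were 6 without control replicate 2, 9 without control replicate 3, 10 without SOX9 siRNA replicate 2 and 8 without SOX9 siRNA replicate 3, in each case higher. CTSH, a cathepsin gene, rose from 3.42 ± 0.922 TPM to 7.46 ± 1.22 TPM (SD, n = 3 per group). LAMP3, a lysosome-associated membrane protein gene, stands among the alveolar markers and not in this list, and it was called 6.19-fold lower. The count of 0 lower thus holds for the list as it was written, not for every lysosomal gene of the table. Of 29 glucocorticoid-induced genes 13 were in the table, with 11 lower, 0 higher and 2 not called (Fisher's exact test, adjusted p = 0.00674), among them ERRFI1, an inhibitor of EGFR signalling, which fell from 230.1 ± 5.42 TPM to 109.4 ± 8.15 TPM, and FKBP5, a co-chaperone of steroid receptors, which fell from 17.2 ± 2.49 TPM to 8.12 ± 2.21 TPM (SD, n = 3 per group). Without control replicate 2 that list did not pass (Fisher's exact test, adjusted p = 0.053), and SOX9 siRNA replicate 2 was the highest of its group in 10 of the 11 lower genes.

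Of 22 genes of MHC class I antigen presentation 12 were in the table, with 11 lower and 1 higher (Fisher's exact test, adjusted p = 0.0215). B2M, the common light chain, fell from 246.1 ± 33.2 TPM to 150.8 ± 31.2 TPM (SD, n = 3 per group), and the higher one was HLA-G, whose reads can be shared with the other class I genes. In all 11 lower genes control replicate 1 was the lowest control library and SOX9 siRNA replicate 2 the highest SOX9 siRNA library, the order also seen in the interferon list, and in HLA-B these libraries stood at 18.16 and 18.14 TPM. On the first principal component, too, they lay nearest to the other group, at -11.1 and 6.88, so the order was not particular to interferon-stimulated genes. The list shares TAP1, PSMB8 and PSMB9 with the interferon list, so the 2 need not be separate findings, and it did not pass without control replicate 2 (Fisher's exact test, adjusted p = 0.285), control replicate 3 (0.269), SOX9 siRNA replicate 1 (0.0505) or SOX9 siRNA replicate 3 (0.0988). Of 35 NRF2 targets 8 were in the table, with 6 higher, 1 lower and 1 not called (Fisher's exact test, adjusted p = 0.048, and 0.0505 with the interferon list out of the comparison genes). HMOX1, the heme oxygenase gene, rose from 12.2 ± 2.19 TPM to 40.3 ± 11.4 TPM (SD, n = 3 per group). The NRF2 list did not pass without control replicate 2 (0.053), SOX9 siRNA replicate 1 (0.0505) or SOX9 siRNA replicate 3 (0.0988), nor on the scaling of the authors' fold changes (0.0779). Of 17 tubulin genes 5 were in the table, with 4 higher and 1 not called (1 call without control replicate 2 or 3, and 2 without SOX9 siRNA replicate 1 or 3), and their near-identical sequences leave single values uncertain. With the p-values adjusted over all 12256 genes, 0 lysosomal, 1 glucocorticoid-induced, 3 MHC class I, 2 NRF2 and 1 tubulin gene were called, fewer than 5 in each list, so their direction could not be tested there. Counting every list gene as tested by the authors, the 40 interferon genes in the table stand against 5.89 expected by chance (hypergeometric upper limit of the adjusted p = 1.51e-31 over 31 lists). Among the other fixed lists, the stress (2.36e-05), matrix (0.00206), squamous (0.00249), inflammatory (0.00977) and aberrant basaloid (0.015) lists also had this limit under 0.05. So did the added MHC class I (0.000123), glucocorticoid-induced (0.000591) and lysosomal (0.00143) lists, and the rest did not. These values, too, count genes as independent, which members that vary together are not.

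The interferon list was lower in the SOX9 siRNA group and also differed between its libraries, replicate 2 lying 1.68 above replicate 3 on the log2(TPM + 0.1) scale in the median (95% bootstrap interval over genes 1.46 to 1.94). Whether residual SOX9 mRNA goes with that difference stays open: SOX9 differed by 0.04 between replicates 2 and 3 and by 0.39 between replicates 2 and 1, the interferon list by 1.68 and 2.45, and differences of 0.87 and 1.27 in SOX9 would be needed at the ratio seen between the groups, which need not hold within a group. RNA of control cells mixed into replicate 2 cannot be told apart from other causes, because the sets of genes disagree. Replicate 2 lay 25.2% of the way from the other SOX9 siRNA libraries to the control mean in the interferon list (20.9 to 31.1), 30.3% in 57 other lower genes (24.4 to 32.7) and 22.7% in 21 other higher genes (-25.7 to 43.1), both of these sets with a log2 fold change of at least 1 in size and a mean of at least 10 TPM, but -41.4% in 13 squamous genes (-287.9 to -5.7). The 57 other lower genes leave out only the members of the interferon list and still hold the interferon-stimulated gene IFITM1. They are therefore not a set free of such genes, and their likeness to the interferon list is not separate evidence of mixing. The squamous list taken alone would exclude mixing, and it was at first the set used to decide, but SOX9 siRNA replicates 1 and 3 lie 42.9% apart in it on the same scale (9.0 to 62.1), and replicate 2 lay above both in 7 of the 13 genes and below both in 3.

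Whether loss of SOX9 itself lowers interferon-stimulated genes stays open. The difference between the groups was -3.07 in the median of the list on the log2(TPM + 0.1) scale (95% bootstrap interval over genes -3.32 to -2.75), and the labels name a single siRNA for each group. Both are labelled stealth siRNA, and the labels do not say whether each was a single duplex or a pool. Double-stranded RNA can set off interferon signalling, and a difference between the siRNAs or their transfections in that respect cannot be told apart from an effect of SOX9, since untransfected cells or a second SOX9 siRNA are not among the samples analysed here. A role of SOX9 in keeping these genes expressed is a hypothesis that was not tested.

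For the lysosomal genes, gene length and expression level were weighed, since the share of higher genes in the authors' deposited table was 41.4% in the fifth of genes with the longest implied length and between 53.1% and 59.8% in the others. All 23 genes of the lysosomal list, which leaves out the lower gene LAMP3, were higher, against a median of 52.2% and a highest share of 87.0% in 10000 sets of table genes matched on length and level (permutation p = 0.0001, the smallest these sets can give). In the 12 bins of length and level that hold lysosomal genes, between 38.5% and 65.6% of the other genes were higher. Genes of such length and level were thus not all higher. The comparison cannot decide further on length or level, because the lysosomal genes were known to lie higher before it was made. The list had been written after its genes were seen to lie higher in the same libraries, so the p-value is no evidence that lysosomal genes as a class rise, and a coordinated rise is a hypothesis that was not tested.

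The 6 libraries can be split into groups of 3 in 10 ways, and 1 of the 10, the real one, gave 1390 calls, while the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached, and the genes had been selected on the real split.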
